A study of Oryza sativa Japonica Group with 36 samples.

How the data were processed

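The study's processed data used here are a single table of the whole series, with genes in rows and 36 columns. Per the submitters' processing notes, the tools included CASAVA 1.8, Trim Galore, TopHat2, SAMtools and HTSeq, with the genome build IRGSP-1.0. The role, order and settings of these tools are not given in the sources used here. No column of values entered any result, and no result here tests whether the values are whole-number read counts.

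Libraries were grouped by genotype and condition from their titles, which gave 12 groups of 3. Each column name was compared with the title, description, source name, characteristics and accession of each library, ignoring letter case and punctuation. A column was to be used only if it matched exactly 1 library. This held for 0 of the 36 columns, and all 36 were left out.

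Before the data were examined, 17 contrasts were fixed together with a rule for the genes to be named, 23 gene lists written by identifier and 18 lists defined by product descriptions. None of the contrasts or list tests was run. The identifiers of the 23 lists were written from general knowledge and compared with the row names, ignoring letter case. They were not checked against an independent source of gene names. The reference gene table used here holds 39387 genes, and 1 of the 35679 row identifiers was found among its identifiers, symbols and synonyms. Only equal names were counted, ignoring letter case, so this number does not show how many genes are in both. The reference gene table has no column of product descriptions, so the 18 lists defined by them were not formed.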

Results

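Polyadenylated RNA was sequenced from whole shoots of young rice plants of the japonica cultivar M202 and of M202(Sub1), a near-isogenic line that carries an introgressed Sub1 locus. The labels describe 36 libraries in 12 groups of 3. Each of the 2 genotypes was sampled at 6 conditions. These were an unsubmerged control, the end of 3 d of complete submergence, and dusk, midnight, dawn and midday of the recovery that followed. The midday sample was taken 24 h after the plants left the water. The labels state a submergence of 72 h, yet they give its start and its end different times of day, so the exact duration is uncertain. The design implies comparisons of submerged with unsubmerged shoots, of recovering with submerged and unsubmerged shoots, and of the genotypes at each condition. The labels place the control, the end of submergence and midday at the same time of day. Dusk, midnight and dawn fall at other times and have no unsubmerged sample. A comparison of these with the control or the end of submergence cannot tell recovery apart from time of day.

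No expression difference is reported here for any gene, group of genes or condition. The table used here has 36 columns of values, which carry only serial numbers as names. None of the 36 column names matched the labels of a single library, so 0 columns could be assigned to a genotype or a condition. The 17 contrasts fixed before the data were examined were therefore not computed. Assigning columns by their order or by the expression of marker genes would have rested on a guess, and neither was done. The depth of each library, the spread between replicates and the response of either genotype to submergence were not analysed here.

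The row names could be read without using any column of values. The table has 35679 gene rows with as many distinct identifiers, and 5 further rows with summary names. Of the 284 members of 23 gene lists fixed by identifier, 282 had a row. All 14 identifiers listed for anaerobic fermentation and hypoxia and all 19 listed for ethylene synthesis and signalling were present. The same held for the 16 of gibberellin metabolism and signalling and the 6 of the SUB1 locus and related ERF genes. That list was limited to SUB1 locus members of the reference genome and related ERF genes. It did not include SUB1A, the submergence tolerance gene of the introgressed locus, and no row was examined for SUB1A. The 2 identifiers without a row belonged to the lists for sucrose and starch breakdown and for nitrogen assimilation and amino acid turnover. The presence of a row shows only that the identifier is in the annotation that was counted. It carries no information on expression, nor on whether the identifier had been paired with the right gene name.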

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

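The alternatives given here were chosen after the column and row names had been seen. The number of columns matched to 1 library was 0 when a name had to equal a whole title. It was also 0 when the column's number was compared with the replicate number in the titles. Of the 36 column numbers, 33 equalled no replicate number, and the other 3 were each shared by 12 libraries. Every replicate number was shared by 12 libraries, so this comparison could not have matched a column to 1 library. The number of list members with a row was 282 when letter case was ignored and 0 when it was kept, because the table writes its identifiers in capitals. No paired analysis was possible because the columns carry no replicate number that ties them to a library. The alternatives planned for the contrasts, which covered normalisation, test, filters, block and left-out libraries, were not run, as there was no contrast to recompute.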
